A study of Physcomitrium patens with 4 samples.

How the data were processed

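The series holds 4 RNA-seq libraries of the moss Physcomitrium patens, strain Gransden, each labelled as biological replicate 1 of its tissue: egg cells at stage 8, egg cells at stage 9, archegonium cavity wall and gametophore shoot apex. Per the labels' protocols, gametangia were induced at 15°C with 8 h of light per day, gametophores were harvested after 19 and 25 days, and cells were cut out by laser microdissection. RNA was amplified from poly(A) tails in 16 cycles with a low-input kit, and libraries were made from the amplified cDNA with a DNA library kit, which does not mark strand. Reads of genes that overlap on opposite strands therefore cannot be assigned by strand.

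The deposited table gives estimated counts per gene ID, rounded to whole numbers and not scaled to depth, together with a length per ID. FastQC, fastp and kallisto are named in the submitters' processing notes. Their versions and settings, the transcript set, the genome build and the way transcripts were summed to genes are not given in the sources used here. Pseudoalignment divides reads that fit several transcripts among them, and 120 measured IDs with at least 20 counts in 2 or more libraries shared all 3 of their counts with another ID. Those IDs held 3.59% of the cavity wall counts, 5.70% of stage 8 and 5.99% of stage 9, and 44 of them were higher in both egg libraries than in the cavity wall. Values of near-identical gene copies are uncertain for this reason.

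Columns were taken only where their name matched the labels of 1 sample, which gave the cavity wall and both egg libraries. The shoot apex library had no column that could be matched in this way and is not analysed here. A further 25 columns of per-library values were not used. One of them, named LCM, may by elimination be the shoot apex library, and the others include libraries re-analysed from another source. The planned rule of egg against both somatic tissues was therefore applied with the cavity wall as the single somatic library, and the planned contrast of cavity wall with shoot apex was not made. Gene IDs have the form Pp3c, a series number from 1 to 27, and a running number, or Pp3s for further scaffolds. In the naming of these gene models the series number stands for the chromosome. The reference table at hand, which is of a recent assembly, contained 0 of the 34840 IDs, so neither gene names nor coordinates are given. The 34 keyword gene lists written before the data were examined could not be applied, and the homologs named in the series title are not reported here.

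Library totals were 8080687 counts for the cavity wall, 8758044 for stage 8 and 14495845 for stage 9. A count of 3, the one-sided 95% upper limit that a count of 0 allows, corresponds to 0.371, 0.343 and 0.207 CPM of these totals. Counts were scaled with TMM factors (edgeR 4.0.16 in R 4.3.3) of 1.165 for the cavity wall, 0.934 for stage 8 and 0.919 for stage 9, and expressed as CPM. No count model was fitted and no test was made, because each group had 1 library. An ID was said to differ when the ratio of scaled counts was at least 4 and the higher library had at least 20 counts, with counts under 3 set to 3. For both egg libraries against the cavity wall, each egg library had to pass. Correlations used log2(CPM + 1). Intervals of ratios are exact conditional binomial (Clopper-Pearson) intervals at 95% and cover counting error only. Named IDs were the 2 highest per direction among those that passed, ranked by the ratio of CPM with 5 added to each. In their ratios only a count of 0 was set to 3. Random sets matched on mean abundance in 20 classes were drawn 10000 times for ID series and 2000 times for neighbouring IDs. Lists matched on length and abundance were drawn 10000 times.

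The rule was tested on simulated data. Counts for all 34840 IDs were drawn around 1 common profile at the real totals, with known sets of IDs changed in both egg libraries. Of 50 IDs made 8-fold higher, 50 were recovered, and of 50 made 8-fold lower, 50 were recovered. Of 50 made 3-fold higher and 50 made 3-fold lower, 0 were called, and 0 of the 34640 unchanged IDs were called. These simulations contain counting error but no variation between replicate libraries.

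Alternatives were library totals, DESeq2 1.42.0 size factors, count minimums of 5 and 100, ratios of 2 and 8, a floor of 1 count, thinning to the smallest total and leaving out each egg library. IDs that share all counts, and IDs whose number is not a multiple of 10, were also left out as alternatives chosen after seeing the data. Figures were drawn with matplotlib 3.10.9, and other calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.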

Results

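RNA was sequenced from laser-microdissected cells of Physcomitrium patens, a moss whose leafy gametophores carry the female organs (archegonia), each of which encloses a single egg cell. Of the 4 libraries of the series, 3 were analysed here: egg cells at stage 8, egg cells at stage 9, and the wall of the archegonium cavity. The shoot apex library was not analysed here, because no column of the table carries a name that matches its labels. By elimination it may be the column named LCM, which was left out because the name does not say so. Each group had 1 library, so every difference given below is a difference between single libraries with no replicate check, and no p-values are given. The libraries held 8080687 estimated counts for the cavity wall, 8758044 for stage 8 and 14495845 for stage 9. Of 34840 gene IDs, 21506 had at least 10 counts summed over the 3 libraries and are called measured below. Neither the table nor the reference table used here pairs these IDs with gene names, so genes are described as groups of IDs, and 2 IDs per direction are named for each of the main contrasts.

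The number of genes detected was similar in the egg cells and the cavity wall. After each library was thinned to 8080687 counts, 19420 IDs had at least 1 count in stage 8, 19106 in stage 9 and 19876 in the cavity wall. At least 20 counts were reached by 15046 IDs in stage 8, 14920 in stage 9 and 16473 in the cavity wall. The top 10 IDs of the cavity wall held 15.2% of its counts, 4.97% of them in a single ID, whereas the top 10 held 9.76% in stage 8 and 10.3% in stage 9. The order differed for the top 1000 IDs, which held 48.7% in the cavity wall, 52.5% in stage 8 and 49.1% in stage 9. The egg stages shared most of their abundant transcripts, with 74 of the 100 most abundant IDs in common, whereas the cavity wall shared 37 with stage 8 and 34 with stage 9. Across the 21506 measured IDs, log2 abundance in stage 8 and stage 9 had a Pearson correlation of 0.72 and a Spearman correlation of 0.70. The corresponding values against the cavity wall were 0.41 and 0.40 for stage 8, and 0.40 and 0.39 for stage 9. These coefficients are across genes, which are not independent replicates.

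The main comparison asked how the transcript content of the egg differs from that of somatic cells of the archegonium. A large part of the transcriptome differed between the egg cells and the cavity wall in the same direction at both stages. In both egg libraries 3020 IDs were at least 4-fold higher than in the cavity wall, which is 14.04% of the measured IDs, and 3596 IDs, 16.7%, were at least 4-fold lower. The egg-higher IDs supplied 28.0% of all counts in stage 8 and 28.7% in stage 9, against 2.40% in the cavity wall. The egg-lower IDs supplied 31.3% of the cavity wall counts, against 1.23% in stage 8 and 1.30% in stage 9. With counts under 3 set to 3, the smaller of the egg-to-wall ratios had a median of 14.2 over the egg-higher IDs, and the smaller of the wall-to-egg ratios had a median of 11.9 over the egg-lower IDs. Of the egg-higher IDs 1408 reached 16-fold and 899 had no count in the cavity wall. Of the egg-lower IDs 1425 reached 16-fold and 897 had no count in either egg library. A count of 0 in the cavity wall allows a level of up to 0.371 CPM (counts scaled to a common total) of its unscaled library total, that of 3 counts.

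Pp3c12_10130, which has a listed length of 1825, ranked first among the egg-higher IDs. It had 12046 counts in stage 8 and 17331 in stage 9 but 34 in the cavity wall, so that it was 408-fold higher in stage 8 (95% counting interval 292 to 589) and 359.99-fold higher in stage 9 (258 to 519.99). Pp3c1_14810 ranked second, with 9548 and 13920 counts in the egg libraries and 21 in the cavity wall. Its ratio to the cavity wall was 523 in stage 8 (342 to 846) and 468 in stage 9 (306 to 756). Among the egg-lower IDs, Pp3c16_11740 ranked first, with 11465 counts in the cavity wall, 17 in stage 8 and 49 in stage 9. It was 586-fold lower in stage 8 than in the cavity wall (366 to 1006) and 331-fold lower in stage 9 (250.4 to 448). Pp3c12_25310 ranked second, with 3784 counts in the cavity wall, 0 in stage 8 and 1 in stage 9. With the count of 0 set to 3, which is a one-sided 95% limit, it was at least 1096-fold lower in stage 8, and the two-sided 95% limit, as used for the other ratios, is 891-fold. In stage 9 it was 5358-fold lower, with a counting interval from 961 to 211687. These exact conditional binomial intervals cover counting error only, and reads made by 16 cycles of amplification are not independent molecules.

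Each egg stage was also compared with the cavity wall on its own. Stage 8 had 4568 IDs at least 4-fold higher and 5471 at least 4-fold lower than the cavity wall. Stage 9 had 4979 higher and 5503 lower. Of the IDs higher in stage 8, 66.1% were also higher in stage 9, and of those lower in stage 8, 65.7% were also lower in stage 9. Independent lists of these sizes would share 1058 higher and 1400 lower IDs, and the 3020 and 3596 observed are 2.86 and 2.57 times as many. In 5 sets of libraries drawn from 1 common profile with counting error only, 0 IDs passed in both stages in either direction. Both contrasts use the same cavity wall library, which could not be split, so part of the overlap may come from that library. Contrasts that share an egg library instead also overlap more than independent lists, by 1.90 and 1.94 times when they share stage 8 and by 1.87 and 2.03 times when they share stage 9, so the excess is not by itself a sign of a common egg profile. Under library totals instead of TMM scaling, the egg-to-wall log2 ratios, averaged over the stages, shift by -0.33, and the share of higher IDs among those that differ in both stages is 39.7% instead of 45.6%.

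**Figure D1:**
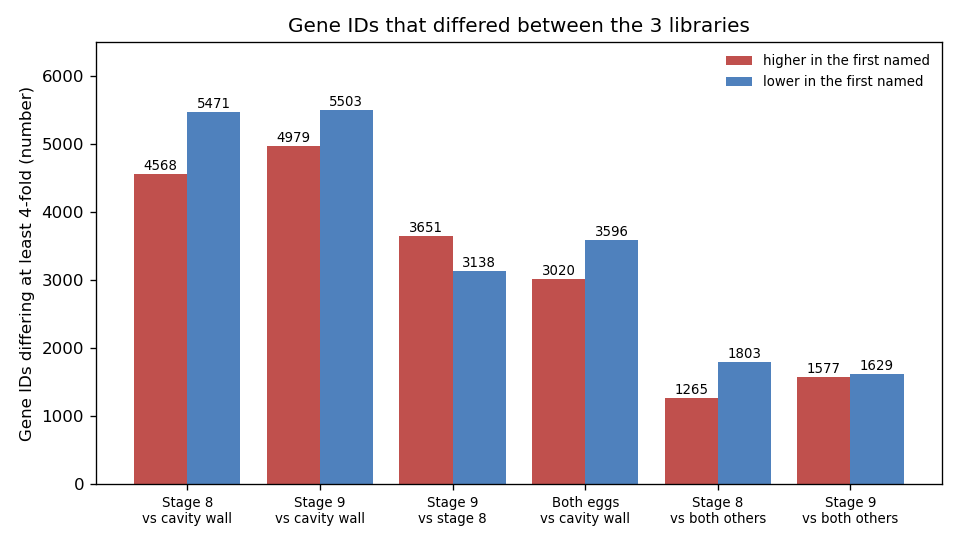
Number of gene IDs (y axis) that differed at least 4-fold in each comparison of the 3 libraries (x axis), red for IDs higher and blue for IDs lower in the first-named library or libraries, with 1 library per group and no error bars. The comparison of both egg libraries with the cavity wall gave 3020 higher and 3596 lower IDs, more than either comparison that sets 1 egg library against both remaining libraries.

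The cavity wall was the most distinct of the 3 libraries. When the same rule was applied with stage 8 set against the other libraries, 1265 IDs were higher in stage 8 than in both and 1803 were lower than in both. With stage 9 set apart, 1577 IDs were higher and 1629 were lower. The corresponding numbers with the cavity wall set apart were 3596 higher and 3020 lower in the cavity wall. Only these 3 ways of setting 1 library apart exist, so they give a description and not a test.

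The last comparison asked what differs between egg stages. Stage 9 and stage 8 differed at least 4-fold in many IDs, of which 3651 were higher and 3138 were lower in stage 9. The IDs higher in stage 9 supplied 11.8% of the counts in stage 9, 1.31% in stage 8 and 9.28% in the cavity wall. The IDs higher in stage 8 supplied 7.98% in stage 8, 0.932% in stage 9 and 8.05% in the cavity wall. Of the 3651 IDs, 1803 were also at least 4-fold higher in the cavity wall than in stage 8. Of the 3138 IDs, 1629 were also at least 4-fold higher in the cavity wall than in stage 9. Many IDs of these sets were thus also present in the cavity wall. Each overlap shares the egg library in which the IDs were low. Such contrasts overlap more than independent lists, by 1.94 times for stage 8 and 2.03 times for stage 9. The overlaps therefore do not tell a stage difference from low values in a single library. When the measured IDs were divided into 10 deciles of mean abundance in the egg libraries, 4.51% of the most abundant decile differed between stages, compared with 47.1% of decile 5 and 61.6% of decile 3. With deciles taken from the mean of egg and wall, the share that differed from the cavity wall in both egg libraries also fell. It was 40.9% in decile 3, 34.1% in decile 5 and 24.1% in decile 8, but 32.9% in the most abundant decile. Both egg libraries had to pass here, so these shares are not directly comparable with those between stages.

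Pp3c24_19200 ranked first among the IDs higher in stage 9, with 3017 counts in stage 9, 2 in stage 8 and 591 in the cavity wall. The ratio of stage 9 to stage 8 was 926, with a counting interval from 256 to 7649. Pp3c7_9540 ranked second, with 4559 counts in stage 9, 24 in stage 8 and 1593 in the cavity wall. Its ratio of stage 9 to stage 8 was 117 (78.3 to 182). Among the IDs lower in stage 9, Pp3c19_14520 had 1364 counts in stage 8, 0 in stage 9 and 1496 in the cavity wall, and was at least 741-fold lower in stage 9 by the same one-sided limit, with a two-sided limit of 602-fold. Pp3c6_27570 had 867 counts in stage 8, 1 in stage 9 and 312 in the cavity wall. Its level was 1413-fold lower in stage 9 than in stage 8, with a counting interval from 253 to 55858. An all-or-none pattern was found in both directions. With the libraries thinned to equal totals, 280 IDs had at least 100 counts in stage 9 and none in stage 8, and 247 had at least 100 counts in stage 8 and none in stage 9. At full depth, where the deeper stage 9 library favours the first number, they were 442 and 242. With 1 library per stage, these numbers hold both the difference between stages and the difference between single libraries.

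**Figure D2:**
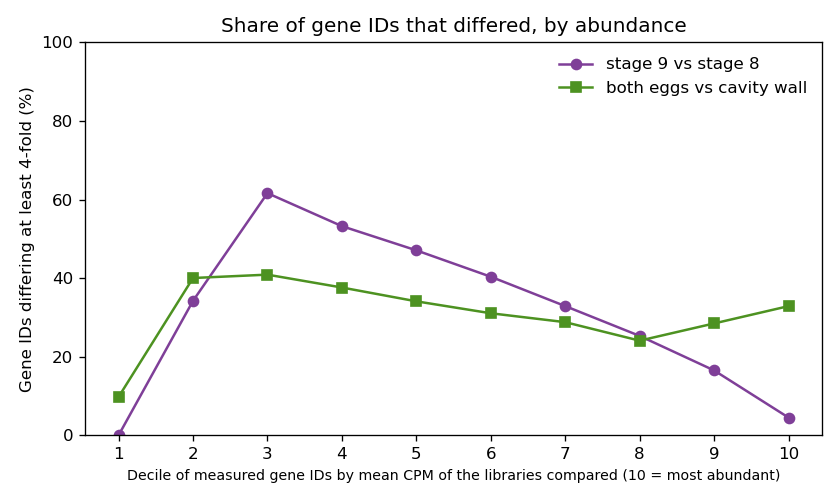
Percentage of gene IDs differing at least 4-fold (y axis) in each decile of the measured IDs ordered by mean CPM of the libraries compared (x axis, 10 is the most abundant decile), purple circles for stage 9 against stage 8 and green squares for both egg libraries against the cavity wall. Between stages the share falls from 61.6% in decile 3 to 4.51% in decile 10, whereas between egg and wall it falls from 40.9% in decile 3 to 24.1% in decile 8 and is 32.9% in decile 10. IDs need at least 20 counts to be called, which few in decile 1 have. Between egg and wall both egg libraries had to pass, whereas between stages 1 library was set against 1, so the curves are not directly comparable.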

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

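Of the tests in this part, the one of counting noise was chosen after the number of stage differences was seen. The egg stages departed from the cavity wall in opposite directions in a small set of IDs. In 77 IDs the level was at least 4-fold higher than the cavity wall in stage 8 and at least 4-fold lower in stage 9. Their median levels were 29.6 CPM in stage 8, 4.68 in the cavity wall and 0.225 in stage 9. In 128 IDs the level was at least 4-fold lower than the cavity wall in stage 8 and at least 4-fold higher in stage 9, with medians of 0.122 in stage 8, 5.53 in the cavity wall and 40.1 in stage 9. These sets were picked out because the single library of each stage moved the opposite way, and the difference itself was not tested.

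These IDs belong to a wider pattern, the 6789 IDs that differed at least 4-fold between stage 9 and stage 8. Counting error of reads alone does not account for it, since at most 6 IDs differed in libraries drawn from 1 common profile. Those draws treat reads as independent and hold no noise from sampling and amplifying few molecules. The greater depth of stage 9 accounts for little of the total, since 6440 IDs differed after thinning to equal totals. It bears more on the direction: 3651 higher and 3138 lower in stage 9 became 3314 higher and 3126 lower. Random loss of transcripts during amplification from few cells stays open: 4.51% of the most abundant decile of IDs differed, against 47.1% of decile 5, as such loss would give, but a stage difference carried by rarer transcripts could give the same. Loss of equal strength in both libraries would also make the directions alike. They were nearly so in decile 5, with 502 IDs higher and 510 lower in stage 9. Abundant IDs were more often higher: 357 against 187 in decile 8, 242 against 113 in decile 9, and 63 against 34 in decile 10. Rarer IDs varied, with 479 higher and 257 lower in decile 2, 605 and 720 in decile 3, and 553 and 592 in decile 4. Equal loss alone would not give the uneven abundant deciles, but these rest on 1 library per stage and were not counted again after thinning. A stronger loss in stage 8 was not tested and stays open. After thinning to equal totals, the values went both ways. More IDs were detected in stage 8 (19420) than in stage 9 (19106). Of IDs with at least 100 counts in the other stage, however, 280 had none in stage 8 and 247 had none in stage 9. These values do not decide between a stronger loss in stage 8 and its absence. A change from stage 8 to stage 9, the difference the design names, is likewise untested, and with 1 library per stage it cannot be told apart from such loss.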

How the results depend on the processing

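Of 88 alternative values for the 12 counts of differing IDs, 80 stayed within 1.5 times the reported count. The 88 include the floor of 1 count, which could move no count. They also include 16 counts from leaving out a small part of the IDs, which left little room to move. The 80 therefore overstate how far the counts were put to a test. Requiring the rule in 1 egg library instead of both raised the egg-higher count from 3020 to between 4568 (without stage 9) and 4979 (without stage 8), and the egg-lower count from 3596 to between 5471 and 5503, as fewer conditions must be met. The contrast of stages moved most with the thresholds. At a ratio of 2, 5776 IDs were higher and 5143 lower in stage 9, and at a ratio of 8, 2167 were higher and 2120 lower. At 100 counts, 2628 were higher and 1788 lower, whereas at 5 counts, 3651 were higher and 3708 lower. These values cannot show whether the excess of IDs higher in stage 9 depends on the count minimum. With stage 8 held at the floor, the required ratio could not be reached below 20 counts in the deeper stage 9 library. At 5 counts the number higher in stage 9 therefore could not change, whereas the number lower could rise. A minimum of 100 counts is a lower scaled level in stage 9 than in stage 8, which favours IDs higher in stage 9. A floor of 1 count changed no count, because with at least 20 counts in the higher library the floor never decides. None of the 12 named ratios changed sign or left its counting interval under library totals or DESeq2 size factors, and the largest shift was 0.34 on the log2 scale. Leaving out IDs with shared counts, or IDs whose number is not a multiple of 10, was chosen after seeing the data. All 16 of its counts, which are among the 88, stayed within 1.5 times. No paired analysis was possible because every library carries replicate number 1 and each group has 1 library. The alternatives that leave out the cavity wall or the shoot apex, and those for the gene lists and for cavity wall against shoot apex, were not run, since the shoot apex library and gene names were not used here. Depth limits the rarer transcripts: IDs with fewer than 20 counts in the higher library could not be called.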

Other observations

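The tests on ID numbering were chosen after its result was seen, whereas the tests on neighbouring IDs were fixed before their results were seen. Egg-higher and egg-lower genes were found in all 27 chromosome series of IDs. The share of measured IDs that were egg-higher ran from 11.1% in series 15 to 17.1% in series 27, and the egg-lower share from 11.99% in series 27 to 21.3% in series 26. Counting all other scaffolds as 1 series, 28 series were compared in each direction. The egg-higher share lay outside the middle 99% of abundance-matched random sets in 1 of them (series 3, 205 of 1209 IDs), and the egg-lower share in 2 (series 10, 172 of 817 IDs, and the other scaffolds, 4 of 80), where chance gives 0.28 per direction. In the shortest of 5 length classes of measured IDs, with listed lengths from 60 to 1222, 16.9% were egg-higher and 12.4% egg-lower, whereas in the middle class 12.9% were egg-higher and 19.0% egg-lower.

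Genes that are next to each other in ID order tended to differ together. There were 568 pairs of neighbouring measured IDs that were both egg-higher, against a median of 428 and a highest value of 491 in 2000 abundance-matched random sets, and 747 egg-lower pairs, against a median of 605 and a highest value of 667. Indistinguishable copies that divide reads evenly do not account for the egg-higher pairs, since 554 pairs were left without those whose counts lay within 10% of each other in both egg libraries, above the highest of their own random sets. Amplification loss shared by neighbours was examined between the egg stages only. The excess there was small: pairs higher in stage 9 than stage 8 exceeded their random median by a factor of 1.05, compared with 1.33 for egg-higher pairs. That contrast leaves out the cavity wall library, in which shared loss would raise egg-higher pairs, so loss in that library stays open. Reads shared by overlapping transcripts cannot be excluded: pairs with 1 measured ID between them numbered 475, above the middle 95% of random sets, which ended at 458, but not above the highest random value of 484. Copies of similar sequence, or joint expression of neighbours in the egg as a hypothesis, also stay open and were not tested.

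IDs whose running number is not a multiple of 10 were more often egg-higher than the others, 24.6% of 1355 IDs against 13.3% of 20151, and 10.4% against 17.1% were egg-lower. They supplied 11.96% of the stage 8 counts and 13.4% of stage 9, against 7.48% of the cavity wall. Without IDs that shared all 3 counts with another ID these shares were 6.85%, 7.83% and 4.41%. Reads divided evenly between indistinguishable IDs do not account for this, since 24.2% were egg-higher among the 1336 IDs left in this way, where shared counts were those with at least 20 in 2 or more libraries. Every egg-higher ID has at least 20 counts in both egg libraries and could be recognised in this way, but an uneven division of reads could not, and stays open. Gene length and abundance do not account for it either, since lists of the other IDs matched on both had a median of 11.4% and a highest value of 14.8%. How these IDs entered the gene set is not given in the sources used here, and no biological explanation was tested.

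At the start of series 20, 27 measured IDs with running numbers below 500 and a median length of 509 supplied 4.17% of the cavity wall counts, 7.16% of stage 8 and 8.12% of stage 9. Of these, 7 were egg-higher and 1 was egg-lower. This set was chosen after its values were seen.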
